A study of Arabidopsis thaliana with 12 samples.

How the data were processed

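RNA from whole seedlings, extracted with Trizol and purified on RNeasy columns per the labels' protocols, was labelled with biotin and hybridised to 12 Affymetrix ATH1 arrays, 3 per group. The values used here are the deposited log2 expression values per probe set, which the authors made with GCRMA and the affy package, per the submitters' processing notes; their versions and settings are not given in the sources used here. That the deposited values are on the log2 scale was checked on the values: they run from 2.14 to 15.6, and 2 raised to the highest gives 48285, under the scanner maximum of 65535. The deposited normalization was kept, no array was left out, and no detection calls were used here. Per-array medians over the 22746 probe sets for genes, before the filter, lay from 5.15 to 5.60. Of these probe sets 34.1% to 36.1% on each array lay below log2 3, close to the background level.

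The table held 22810 probe sets, of which 64 Affymetrix control probe sets were left out of all tests. Probe sets were kept if at least 3 of the 12 arrays reached log2 4, which left 14401. Gene names came from the given platform table and from RefSeq gene rows of assembly TAIR10.1, used for names only. Of 22746 probe sets, 13513 named 1 gene (13436 matched RefSeq, 77 carried the platform name alone), 503 named several and 8730 were unnamed here; 7705, 310 and 6386 of these were kept. Unnamed probe sets were tested and counted, and their genes are not analysed here.

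Group means were compared with limma 3.58.1 (R 4.3.3, statmod 1.5.0) by lmFit and eBayes on all 12 arrays with 1 shared residual variance per probe set and no covariate, two-sided, at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. The comparisons were ABA with control, DFPM with control, ABA+DFPM with ABA, with DFPM and with control, and the interaction, the ABA effect with DFPM minus that without. Retention of the ABA response was the slope through the origin of the ABA effect with DFPM on that without, with probe sets called without the control and ABA arrays of 1 number and the effect without DFPM measured in those left out, averaged over the 3 numbers. The groups, comparisons, tests, gene lists, filter, most alternatives and the rule for named genes were chosen before the data were examined. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures.

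The rule named, in each of 4 comparisons, the 10 most positive and 10 most negative changes among called probe sets of 1 gene, with non-overlapping groups except for the interaction, up to 4 called members of each fixed list, and a set of marker genes, of which COR15A alone is named here and the others are not analysed here. In all, 20 lists with 273 members were fixed: 18 pathways and 2 cell types, root and guard cell, since whole seedlings hold both. Of the members 28 had a named probe set that was kept, and 3 lists had the 3 needed for a test: ABA-inducible stress genes (4 of 20), pattern-triggered immunity (6 of 22) and xenobiotic detoxification (4 of 22). For EDS1 and salicylic acid immunity, jasmonate, auxin, oxidative stress, heat shock, photosynthesis, reference genes, root and guard cell markers, 1 or 2 members were measured and are given singly. For the PP2C phosphatases, PYR/PYL receptors, ABA kinases and transcription factors, ABA synthesis, resistance genes, camalexin, ethylene and cell cycle, 0 members had a named probe set that was kept. These lists are therefore not analysed here, which does not mean that their genes were absent from the array. Lists were tested with camera at a preset correlation of 0.01, adjusted over 12 tests, beside camera with an estimated correlation and fry.

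A further 42 gene families were written from symbols after the annotation coverage was seen, and those with at least 5 measured members were tested the same way, adjusted over 144 tests. Where comparisons shared the control arrays, the chance value came from 100 simulated draws of unchanged groups against simulated shared controls, with probe sets drawn independently. For shared calls, a simulation chosen after the data were seen kept the called ABA effects and moved those of DFPM to other probe sets of similar spread.

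The replicate numbers in the sample titles recur in all groups. Deviations from the group means correlated in each of the 18 pairs of arrays with the same number, with r from 0.426 to 0.802, so the numbers were taken to pair the arrays by a rule set beforehand, though no label says what a number stands for. For arrays numbered 3 against those numbered 1 and 2 of other groups r was -0.766 to -0.432, while for number 1 against number 2 it was 0.380 to 0.701, and 11 of 12 arrays matched their own number best. Within groups, numbers 1 and 2 differed by a median of 0.156 to 0.205 on the log2 scale. For either against number 3 the median was 0.433 to 0.575. At most 1.17% of values were identical between numbers 1 and 2, which excludes copied values but not repeat arrays of 1 sample. Numbers 1 and 2 were counted as separate samples without proof that they were, and counts with both averaged are given beside the main ones. The fit with the number as a block is given where it changed a call or moved a count by over 1.5 times.

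The limma calls were tested on simulated data with 200 changed probe sets of 14401. Camera and the slope were tested on separate simulated data, in which for the slope all 14401 probe sets carried their observed ABA effect. For ABA with control 31% of 2-fold and 61% of 4-fold changes were recovered, with 9 false calls of 101; for DFPM with control 16% and 57% (5 of 78); for ABA+DFPM with ABA 24% and 58% (5 of 87); for the interaction 4% and 40% (1 of 45). Camera recovered 5 of 5 shifted sets of 50 with 0 false. Probe sets were simulated independently, so this does not show how often camera errs for correlated genes. The planned slope came out at 0.889, 0.627 and 0.353 for true slopes of 1, 0.7 and 0.4, so a version that uses the effect in the calling arrays as an instrument was added, which gave 0.989, 0.701 and 0.392. The simulated noise was independent between arrays, while the real arrays numbered 1 and 2 were close to each other. The simulation therefore does not show that the correction is complete in the real data.

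Alternatives were no filter and a filter at log2 6, repeated quantile normalization, median centring, trended and robust variance models, array weights, the block, adjusted p under 0.01, a 2-fold minimum, probe sets of 1 gene, only the groups compared, and each array left out. Those added after seeing the data were the arrays numbered 1 and 2 alone, their average with the block, number 3 as a block, the sign in number 3 of calls made in the others, the instrumented slopes and the families.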

Results

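Gene expression was measured with 1-colour Affymetrix ATH1 arrays in whole Arabidopsis thaliana seedlings of the Col-0 ecotype, 12 days old and raised on plates. The 12 arrays fell into 4 groups of 3: solvent control, abscisic acid (ABA, the hormone of drought and seed responses, 10 µM), the synthetic furan compound DFPM (30 µM), and ABA with DFPM. The labels gave 6 h of treatment and placed the addition of DFPM 30 min ahead of ABA. Of the 22746 probe sets for genes, 14401 were expressed above a set minimum and tested, and the number of arrays limits the precision of every comparison. Changes are given as log2 fold changes ± SE from limma with n = 3 arrays per group, and p-values are adjusted by the Benjamini-Hochberg method. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. In each group the arrays numbered 1 and 2 were close to each other, with r from 0.987 to 0.992 across probe sets, and the array numbered 3 stood apart, with r from 0.875 to 0.920.

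**Figure D1:**
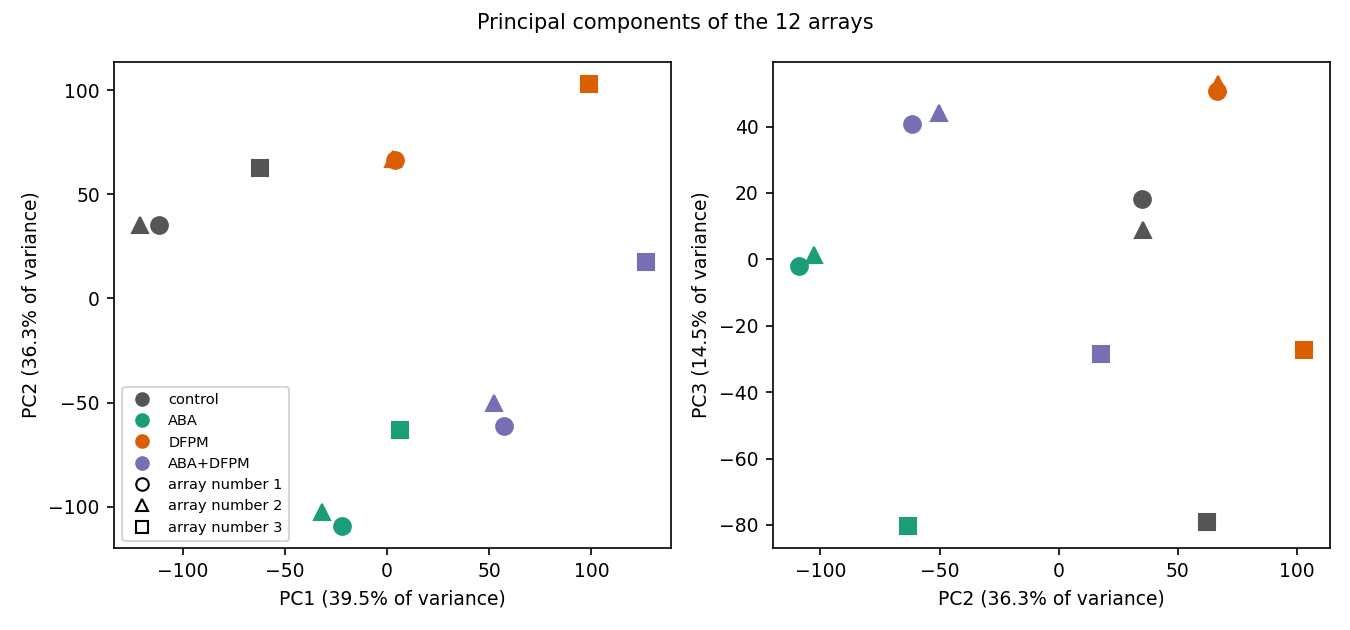
Principal components of the 14401 probe sets tested, with each point 1 array, colour the group and shape the replicate number. The first component holds 39.5% of the variance, the second 36.3% and the third 14.5%, and the arrays numbered 3 lie away from those numbered 1 and 2 in all 4 groups.

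The comparison of ABA with control asked what the hormone alone did after 6 h. The largest rises took genes from near the bottom of the array scale to high levels. COR15A, which encodes a chloroplast protein that protects membranes during freezing, went from a mean log2 level of 3.07 to 12.68, a change of 9.60 ± 0.36 or 777-fold (n = 3, limma, adjusted p = 1.22e-07). LEA4-5, a late embryogenesis abundant protein, rose by 9.29 ± 0.29, and the sugar transporter gene SAG29 (SWEET15) by 9.68 ± 0.51. The small heat shock protein gene HSP22 rose by 5.37 ± 0.52 (adjusted p = 6.71e-05). In the other direction UGT72E1, a UDP-glycosyltransferase, fell from 11.15 to 4.77, a change of -6.38 ± 0.40 (adjusted p = 3.29e-06), and the peroxidase gene Prx37 changed by -5.59 ± 1.18 (adjusted p = 0.0064).

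Among named genes, the largest rise with ABA was that of AT3G02480, by 11.42 ± 0.18, and AT3G17520, AT2G41190, EXPA16 (an expansin), AT1G09500, AT3G15670 and AT1G49450 rose by 9.40, 8.31, 8.19, 8.16, 8.07 and 7.94. The steepest falls of named genes were those of AT5G48430 (-6.88 ± 0.80) and AT2G17740 (-6.75 ± 0.67), and AT3G23550, AT1G66940, AT4G21870, AT5G62360, AT2G43140 and AT3G10120 changed by -6.14, -6.04, -6.00, -5.54, -5.48 and -5.40. In 15 of these 20 genes the lower of both group means was under log2 4, where the background correction sets the value, so their fold changes are less certain than their directions.

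Among the 4 measured ABA-inducible stress genes, 3 rose with ABA, and 3 also passed adjusted over the list alone. COR15A was joined by its neighbour COR15B at 3.94 ± 0.39 and by the dehydrin gene COR47 at 2.56 ± 0.24, while XERICO, which raises ABA levels when overexpressed, gave 0.73 ± 0.52 (adjusted p = 0.326, or 0.0040 with the replicate number as a block). As a set they passed limma's camera test at adjusted p = 2.08e-04, with adjusted p = 0.170 with an estimated correlation. All 6 measured members of the pattern-triggered immunity list fell with ABA, and 6 passed adjusted over the list alone. They were the ubiquitin ligase genes PUB22 (-2.69 ± 0.46) and PUB23 (-2.15 ± 0.44), known to dampen this response, the transcription factor genes WRKY53 (-2.23 ± 0.68) and WRKY22 (-2.15 ± 0.71), the kinase gene BIK1 (-1.28 ± 0.29) and the receptor gene EFR (-0.87 ± 0.19). The set passed camera at adjusted p = 0.0025, with adjusted p = 0.170 with an estimated correlation.

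Of 4 measured xenobiotic detoxification genes 2 rose with ABA, the glutathione transferase gene GSTU22 by 2.3 ± 0.32 and the glycosyltransferase gene UGT73B5 by 1.32 ± 0.42, and 2 passed adjusted over the list alone. UGT73B4 gave 1.04 ± 0.77 (adjusted p = 0.343, blocked 0.0083) and GSTU25 -0.27 ± 1.22, and the list did not pass camera (adjusted p = 0.0801). The defensin gene PDF1.2, the only measured jasmonate gene, fell by 2.97. Neither measured gene of salicylic acid immunity passed (GRX480 -1.09, blocked adjusted p = 0.0175, and SAG101 -0.50), and neither did the auxin genes GH3.5 (1.17) and GH3.3 (-1.30), the photosynthesis genes LHCB4.1 (-0.53) and RCA (-0.88), the oxidative stress gene ZAT10 (-1.24, blocked adjusted p = 0.0087), the root genes EXP7 (0.02) and EXP18 (-0.43) or the guard cell gene FAMA (-0.77, blocked adjusted p = 0.0443). Of the reference genes, TIP41 gave -0.29 and SAND 0.43 (adjusted p = 0.0713, blocked 0.0406), and SAND was the 1 that passed adjusted over the list alone.

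With ABA 4165 of 14401 probe sets passed the limma test, 2099 higher and 2066 lower, and 6982 did with the block, or 3365 with numbers 1 and 2 averaged and the block kept, a design chosen after the data were seen. Arrays of the groups did not overlap for 46.8% of probe sets, where chance gives 10%. The median size of the called changes was 1.5 in the arrays numbered 1 and 2 and 1.24 in those numbered 3. Of 8364 probe sets called in numbers 1 and 2 alone, 93.5% had the same sign in number 3. The 3' minus 5' differences of 2 of 3 control genes, a sign of RNA integrity, moved with ABA. For ubiquitin the difference was 1.03 to 1.29 in control arrays, 0.61 to 0.82 with ABA, 1.04 to 1.25 with DFPM and 0.73 to 0.97 with both. For actin it was 4.86 to 5.30, 4.56 to 4.63, 4.86 to 5.05 and 4.27 to 4.68 in the same order, and for GAPDH the ranges of control and ABA overlapped, at 1.09 to 1.31 and 1.24 to 1.32. The count fell to 2746 without control replicate 2, 2402 without ABA replicate 1 and 2676 without ABA replicate 2. Single arrays left out also ended calls: of WRKY53 without control 1 or 3 or ABA 1 or 2 (adjusted p 0.0948 to 0.126), of PDF1.2 without control 2 or ABA 1 or 2 (0.0639 to 0.0765), of WRKY22 without any array but ABA 2 or DFPM 2 or 3 (0.0539 to 0.138), and of UGT73B5 without any control array, ABA 1 or 3, DFPM 1 or ABA+DFPM 1 (0.0551 to 0.127).

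**Figure D2:**
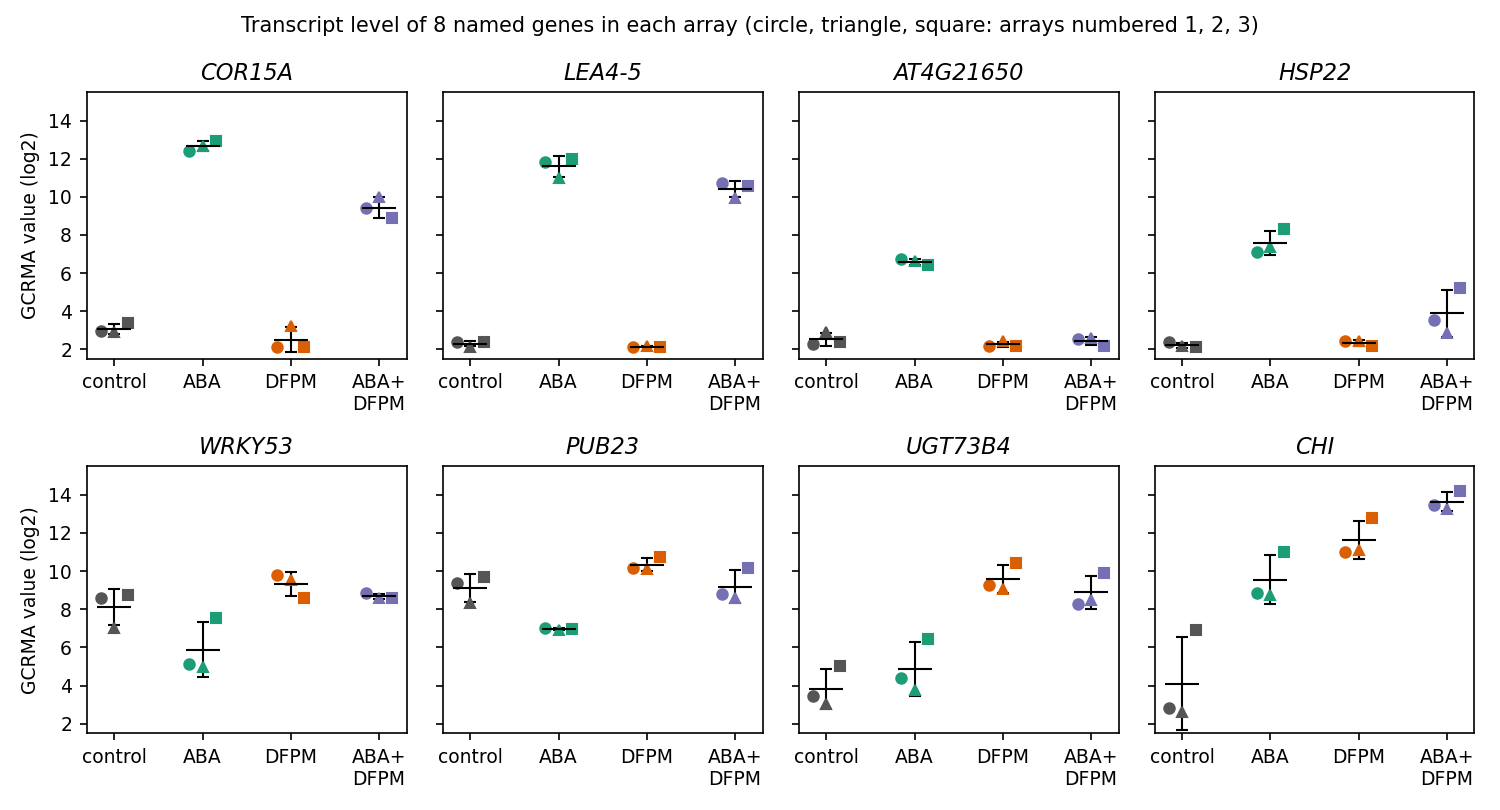
Log2 expression of 8 genes (COR15A, LEA4-5, AT4G21650, HSP22, WRKY53, PUB23, UGT73B4 and CHI) in the 4 groups, with points for arrays, bars at group means and whiskers of 1 SD (n = 3). COR15A stood at 3.07 in control, 12.68 with ABA, 2.51 with DFPM and 9.43 with both, and UGT73B4 at 3.83, 4.88, 9.59 and 8.89.

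The comparison of DFPM with control asked what the compound did in seedlings given no ABA. The chitinase gene CHI went from 4.1 to 11.62, a change of 7.52 ± 1.08 (n = 3, limma, adjusted p = 0.0013), the peroxidase gene PRX52 rose by 6.61 ± 0.74, and the glycosyltransferase genes UGT73D1 and UGT73B4 rose by 6.23 ± 0.77 and 5.75 ± 0.77. GSTU22 rose by 4.40 ± 0.32 (adjusted p = 4.81e-05). BCAT4, an aminotransferase of methionine-derived glucosinolate synthesis, fell from 7.51 to 2.25, a change of -5.26 ± 0.43 (adjusted p = 7.81e-05). The deepest fall was that of AT2G10940, from 10.94 to 3.23, or -7.71 ± 0.22 (adjusted p = 1.11e-07).

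Of the named genes, those next to CHI in size with DFPM were AT1G57630 (6.90 ± 0.73), AT1G26410 (6.73 ± 0.55) and AT4G37290 (6.65 ± 1.09), and AT5G38900, AT5G22530, AT3G47540 and AT3G48640 rose by 6.43, 6.23, 6.22 and 6.19. AT1G09750, AT2G33850, AT5G62360, AT5G57760, AT5G48490, AT1G15260, AT3G16370 and AT5G55220 changed by -5.25, -4.49, -4.43, -4.29, -3.91, -3.78, -3.69 and -3.69, and the last lost its call without control replicate 2 (adjusted p = 0.0632). The lower group mean was under log2 4 in 11 of these 20 genes.

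Of the 4 measured xenobiotic detoxification genes, 3 rose with DFPM and 4 passed adjusted over the list alone. Beside UGT73B4 and GSTU22 these were UGT73B5 (3.51 ± 0.42) and, over the list alone, GSTU25 (3.70 ± 1.22, adjusted p = 0.0514 over all probe sets, blocked 2.45e-05). The list passed camera at adjusted p = 2.08e-04, with adjusted p = 0.170 with an estimated correlation. Only 4 of its 22 members were measured, so it does not stand for all detoxification genes. Over 8 measured tau-class glutathione transferase genes, GSTU22 and GSTU25 among them, the median with DFPM was -0.35. Both measured genes of salicylic acid immunity rose, the glutaredoxin gene GRX480 by 4.01 ± 1.22 and the EDS1 partner gene SAG101 by 1.19 ± 0.27, and 2 passed adjusted over the list alone. In the pattern-triggered immunity list 1 of 6 rose, EFR by 1.28 ± 0.19 (adjusted p = 0.0016), and 3 passed adjusted over the list alone. PUB23 gave 1.22 (blocked adjusted p = 0.0125), WRKY53 1.2, BIK1 0.79, PUB22 0.48 and WRKY22 -0.30, and the set passed camera at adjusted p = 0.0358, but at 0.0593 with the block and with adjusted p = 0.257 with an estimated correlation.

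Of the 4 measured ABA-inducible stress genes 2 fell with DFPM alone, COR15B with a change of -2.11 ± 0.39 and COR47 with -1.03 ± 0.24, and 2 passed adjusted over the list alone. COR15A gave -0.57 ± 0.36 and XERICO -1.04 ± 0.52 (adjusted p = 0.171, blocked 9.05e-04), and camera gave adjusted p = 0.0289, with adjusted p = 0.224 with an estimated correlation. The auxin-conjugating enzyme gene GH3.3 rose by 3.94 ± 0.78, while GH3.5 gave -2.48 ± 1.17 (blocked adjusted p = 0.0056). The root expansin gene EXP18 fell by 1.17, and EXP7 (-0.74) passed with the block only. The photosynthesis genes RCA (-2.07 ± 0.93, blocked adjusted p = 0.0210) and LHCB4.1 (-1.59 ± 0.84, blocked 0.0156) passed with the block only, as did ZAT10 (1.06, blocked 0.0184). PDF1.2 (1.36), HSP22 (0.11), FAMA (-0.23), SAND (-0.12) and TIP41 (-0.05) did not pass.

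With DFPM 3463 of 14401 probe sets passed, 1827 higher and 1636 lower, and 6821 did with the block, or 3472 with numbers 1 and 2 averaged. The groups did not overlap for 44.3% of probe sets, where chance gives 10% for independent arrays. The median size of the called changes was 1.3 in the arrays numbered 1 and 2 and 1.63 in those numbered 3. The count fell to 1981 without control replicate 2. The immunity list's test rose to 0.0900, 0.0556, 0.0534 and 0.0713 without control replicates 2 and 3 and DFPM replicates 1 and 2. The call of GRX480 was lost without control 1 or 2, ABA 1 or 2 or any DFPM array (adjusted p 0.0521 to 0.128), and that of EXP18 without control 2 or 3, ABA 1, or DFPM 1 or 2 (0.0509 to 0.0996).

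The effects of ABA and of DFPM had r = 0.282 (rho = 0.389) across probe sets, which are not independent replicates. Both were measured against the same 3 control arrays, and simulated groups with no effect and with shared simulated controls gave r = 0.499. Shared controls of equal spread fix that value in advance. The covariance was 0.467, against 0.0521 in the simulation, a difference of 0.415, or 0.327 where the simulated spread included that between replicate numbers. The share of probe sets with the same sign for ABA and DFPM was 66.6%, and it was 66.6% under either simulated spread. Shared controls without effects fix that share in advance, and the real groups held many effects. Signs over all probe sets therefore cannot show whether both effects went together. Together 805 probe sets fell in both comparisons and 553 rose in both, while 99 rose with ABA and fell with DFPM and 172 fell with ABA and rose with DFPM. In 100 draws with shared simulated controls and unrelated effects, these numbers averaged 197, 226, 186 and 188 and reached at most 238, 255, 223 and 219. Calls were somewhat fewer there, 3626 for ABA and 2952 for DFPM. Probe sets were drawn independently, so correlated error in the real controls could give a wider range. With 3 control arrays no split into parts of at least 2 was possible, so part of the excess may come from the shared controls.

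The comparison of ABA+DFPM with ABA asked what the compound changed in seedlings that were also given the hormone. COR15A fell from 12.68 to 9.43, a change of -3.24 ± 0.36 (n = 3, limma, adjusted p = 5.42e-04), and HSP22 from 7.59 to 3.88, a change of -3.71 ± 0.52 (adjusted p = 0.0019). AT4G21650 returned from 6.60 to 2.44, near its control level of 2.52 (-4.16 ± 0.21, adjusted p = 1.56e-05). CCOAMT, a caffeoyl-CoA methyltransferase, rose by 7.19 ± 0.77, the defensin gene LCR67 by 6.74 ± 0.62 and the beta-glucosidase gene BGLU27 by 6.12 ± 0.39. WRKY53 rose from 5.89 to 8.67 and PUB23 from 6.97 to 9.19, toward their control levels of 8.12 and 9.12.

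All 4 xenobiotic detoxification genes rose, with 4 also adjusted over the list alone: GSTU25 by 4.73 ± 1.22, UGT73B4 by 4.01 ± 0.77, GSTU22 by 2.86 ± 0.32 and UGT73B5 by 2.49 ± 0.42 (camera, adjusted p = 1.97e-04, with adjusted p = 0.170 with an estimated correlation). In the pattern-triggered immunity list 2 of 6 rose, WRKY53 by 2.79 ± 0.68 and PUB23 by 2.21 ± 0.44, and 4 passed adjusted over the list alone. PUB22 gave 1.31, BIK1 0.85, WRKY22 0.61 and EFR 0.12, and camera gave adjusted p = 0.0052, with adjusted p = 0.170 with an estimated correlation. Of the ABA-inducible stress genes 2 of 4 fell, COR15A and COR15B (-1.68 ± 0.39), and 3 passed adjusted over the list alone. COR47 stayed within its error at -0.08 ± 0.24, XERICO gave -1.32 (adjusted p = 0.130, blocked 4.16e-04), and camera gave adjusted p = 0.0136, with adjusted p = 0.174 with an estimated correlation.

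GRX480 gave 3.87 ± 1.22 (adjusted p = 0.0660, blocked 6.70e-05) and SAG101 0.81 ± 0.27 (adjusted p = 0.0783, blocked 0.0419), and 2 of this pair passed adjusted over the list alone. GH3.3 rose by 2.84 ± 0.78, GH3.5 gave -1.48, EXP18 changed by -1.29 ± 0.35 and EXP7 gave -1.11 (blocked adjusted p = 0.0155). ZAT10 gave 1.60 (blocked 0.0048), RCA -1.95 (blocked 0.0384), LHCB4.1 -1.05, PDF1.2 1.26, FAMA -0.01, SAND 0.01 and TIP41 0.00. Further rises were those of AT1G26410 (6.67), UGT73D1 (6.38), AT4G37290 (6.10), AT3G13610 (5.98), AT3G09405 (5.93), AT5G38900 (5.90) and AT1G57630 (5.53). AT2G10940 changed by -4.98 ± 0.22, and AT3G16370, AT1G12845, AT1G75900, AT1G15260, AT5G48490, AT1G09750, AT3G54400 and the sugar transporter gene SWEET1 by -4.46, -4.32, -4.29, -4.25, -4.20, -4.13, -3.97 and -3.91. The lower group mean was under log2 4 in 11 of the 20 named genes with the largest changes.

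In this comparison 1814 probe sets passed, 956 higher and 858 lower, and 4486 did with the block, or 1384 with numbers 1 and 2 averaged. The groups did not overlap for 35.8% of probe sets, where chance gives 10% for independent arrays. The median size of the called changes was 1.44 in the arrays numbered 1 and 2 and 1.77 in those numbered 3. The count fell to 945 and 904 without ABA replicates 1 and 2. Without ABA 1 or 2 the calls of WRKY53, GSTU25, GH3.3, EXP18, SWEET1, AT3G13610 and AT1G09750 were lost, the last with adjusted p up to 0.0720 and AT3G13610 up to 0.0509, and without ABA 2 or 3 that of COR15B (0.0674 to 0.0709). Further arrays ended the calls of WRKY53 (any ABA+DFPM array, highest adjusted p 0.0966), GSTU25 (ABA+DFPM 2 or 3, 0.116), SWEET1 (ABA 3, ABA+DFPM 2 or 3, 0.0909), GH3.3 (ABA 3, control or DFPM 1 or 2, 0.120) and EXP18 (ABA 3, control 2, DFPM 1 or 2, ABA+DFPM 2 or 3, 0.116).

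The comparison of ABA+DFPM with DFPM asked what ABA did when DFPM was present. COR15A rose by 6.93 ± 0.36 (n = 3, limma, adjusted p = 1.89e-06), its neighbour COR15B by 4.37 ± 0.39, COR47 by 3.51 ± 0.24 and LEA4-5 by 8.27 ± 0.29. UGT72E1 again fell, with a change of -5.48, and EFR changed by -2.02 ± 0.19 (adjusted p = 1.26e-04). In all, 2049 probe sets passed, 1158 higher and 891 lower, and 5069 did with the block, or 813 with numbers 1 and 2 averaged. The groups did not overlap for 32.5% of probe sets, where chance gives 10% for independent arrays. The median size of the called changes was 1.53 in the arrays numbered 1 and 2 and 1.00 in those numbered 3. Without DFPM replicates 1 and 2 the count was 959 and 925, and without ABA+DFPM replicates 1, 2 and 3 it was 806, 914 and 3246.

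The comparison of ABA+DFPM with control asked what both treatments did together. COR15A was higher by 6.36 ± 0.36 (n = 3, limma, adjusted p = 2.09e-06), CHI by 9.54 ± 1.08 and GSTU22 by 5.15 ± 0.32, while BCAT4 was changed by -5.37 ± 0.43 and AT2G10940 by -7.54 ± 0.22. WRKY53 gave 0.55 ± 0.68 and PUB23 0.07 ± 0.44, with adjusted p = 0.525 and 0.914. In all, 6833 probe sets passed, 3172 higher and 3661 lower, and 6756 did with the block and numbers 1 and 2 averaged. The groups did not overlap for 56.1% of probe sets, where chance gives 10% for independent arrays. The median size of the called changes was 1.58 in the arrays numbered 1 and 2 and 1.44 in those numbered 3.

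The interaction asked directly whether the ABA effect differed with and without DFPM, and 54 probe sets passed, 22 above 0 and 32 below. AT4G21650 rose with ABA alone and stood at 2.44 with both (interaction -3.90 ± 0.30, n = 3, limma, adjusted p = 5.26e-04), and AT5G42290 went from 5.88 with ABA to 2.32 with both (-3.80 ± 0.37, adjusted p = 0.0015). AT1G07690 rose with DFPM alone, to 7.24, and stood at 2.82 with both (-4.33 ± 0.47). Among named genes, BCAT4 had the largest positive value, 4.91 ± 0.61 (adjusted p = 0.0068): it went from 7.51 in control to 2.49 with ABA, 2.25 with DFPM and 2.14 with both. AT2G43580 stood at 2.14 in control, 2.15 with ABA, 2.29 with DFPM and 4.90 with both, and had an interaction of 2.59 ± 0.23 (adjusted p = 0.0011).

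COR15A gave -2.68 ± 0.51 and HSP22 -3.82 ± 0.74, with adjusted p = 0.0641 and 0.0661, and passed with the block at 0.0315 and 0.0288. From their control levels of 3.07 and 2.23, the DFPM effect seen with ABA would lead to -0.17 and -1.49, under the lowest value of the scale, 2.14, so a fall of that size could not show without ABA. No member of the 3 lists with at least 3 measured genes passed. The xenobiotic detoxification list gave a camera adjusted p of 0.0289 below 0, with adjusted p = 0.315 with an estimated correlation and 1 member that fell adjusted over the list alone, GSTU22 (-1.54 ± 0.46). The immunity and ABA lists gave 0.408 and 0.761, where 1 member of the first fell (EFR, -1.15 ± 0.27) and in the second 1 rose (COR47, 0.95 ± 0.34) and 1 fell (COR15A) adjusted over the list alone, and the ABA list's median of 0.07 had the other sign from its mean of -0.39. With the block 202 probe sets passed, and 0 did with numbers 1 and 2 averaged. The count was 30 and 91 without control replicates 2 and 3, 27 and 35 without ABA replicates 1 and 2, and 33 and 30 without DFPM replicates 1 and 2, and the detoxification list's test rose to between 0.0558 and 0.195 without control replicate 1 or 2, ABA replicate 3, DFPM replicate 3 or ABA+DFPM replicate 1 or 2.

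**Figure D3:**
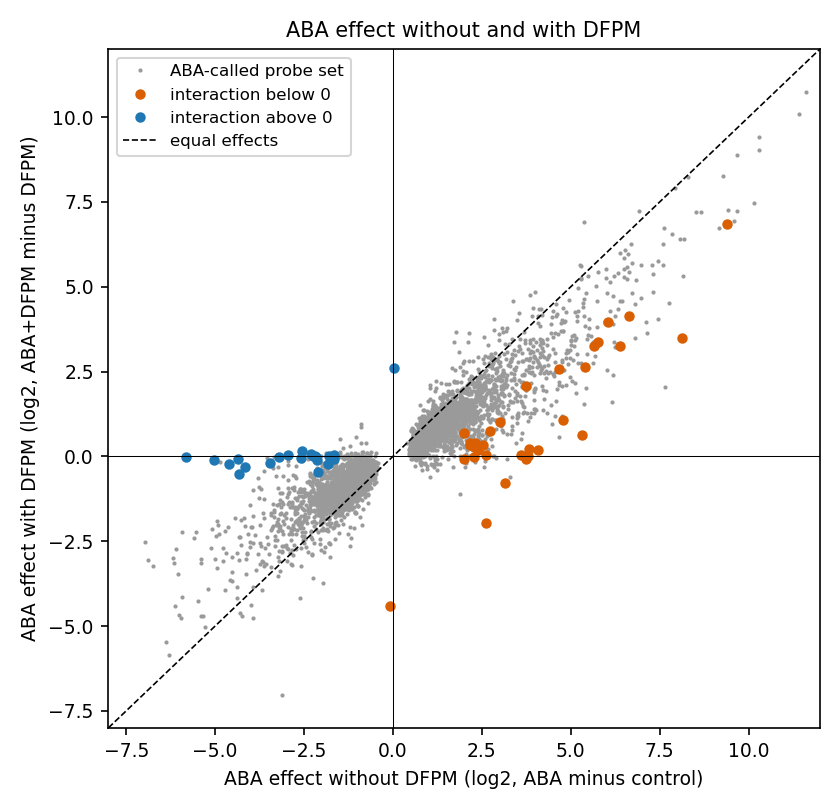
Log2 ABA effect with DFPM (vertical) against that without (horizontal), with grey points the probe sets called for ABA and coloured points the 54 interaction calls. The cross-fitted slope was 0.657, and 32 interaction calls lie below 0 and 22 above.

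Across probe sets called for ABA, the response kept its direction and was smaller with DFPM present. Of 2099 probe sets that rose with ABA, 97.3% had the same sign with DFPM, 86.9% a smaller effect and 1044 a call in the same direction, and the median went from 1.61 to 1.07. Of 2066 that fell, 97.4% had the same sign, 87.2% a smaller effect and 702 a call, and the median went from -1.30 to -0.87. Those medians favour a smaller second value because the probe sets were chosen on the first, so the slope was cross-fitted: the ABA effect with DFPM was 0.657 of that without (SD 0.0374 over 3 rounds), or 0.690 (SD 0.0685) with a correction for measurement error. The correction may be incomplete, as error shared by numbers 1 and 2 would remain. The DFPM effect was likewise smaller with ABA present, with slopes of 0.691 (SD 0.0701) and 0.740 (SD 0.0548), a value with no test. With number 1, 2 and 3 held out, the slope with the correction was 0.637, 0.665 and 0.767 for ABA. For DFPM it was 0.799, 0.728 and 0.691 in the same order.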

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

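Of the tests in this part, those of the lower and upper ends of the array scale and of RNA integrity were chosen after the results were seen, and the reshuffle within replicate numbers was added after the result without it was known. Every gene value in the next paragraph was singled out because the ABA effect differed with and without DFPM by a test of the difference itself, the limma interaction, which 54 probe sets passed.

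Among genes below 0, the values were -4.33 for AT1G07690, -3.90 for AT4G21650, -3.80 for AT5G42290, -3.69 for AT4G34320, -3.62 for AT1G27461, -3.14 for AT2G21820, -2.75 for AT5G02230, -2.57 for AT2G40435, -2.55 for AT3G17520 and -2.51 for AT5G07330. Among genes above 0, they were 4.91 for BCAT4, 3.19 for AT5G62280, 3.02 for AT1G14960, 2.73 for AT2G10940, 2.59 for AT2G43580, 2.35 for AT1G33170, 2.15 for AT3G21300, 1.70 for AT4G20430, 1.65 for AT1G31710 and 1.57 for AT5G48360. Leaving out 1 array ended the call of AT2G21820 (control 2, adjusted p = 0.0509), AT4G20430 (ABA 1, 0.0537), AT1G31710 (control 2, ABA 1, DFPM 1 or 2 or ABA+DFPM 1, up to 0.0657) and AT5G62280 (control 2, ABA 1 or 2, DFPM 1 or 2 or ABA+DFPM 1, up to 0.0607). For AT1G27461 any array but control 3, ABA 2 or 3 or ABA+DFPM 3 did so (up to 0.102), for AT3G21300 any but control 1 or 3 or ABA+DFPM 2 (up to 0.103), for AT5G02230 any but ABA 3 or ABA+DFPM 2 (up to 0.148), and for AT5G48360 any but control 3 or ABA 3 (up to 0.115).

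For 21 of the 22 above 0, the sum of both single effects would lie under the lowest value of the array scale, so a limit of the scale may account for them; AT2G43580 was the exception. Below 0, the limit would act another way, by hiding a fall in the group with 1 treatment. For 24 of the 32, the DFPM effect seen with ABA, or the ABA effect seen with DFPM, would end under the lowest value without the other treatment, so the limit may account for these too. Of the 32, 31 had risen with ABA alone, with a median effect of 3.73 without DFPM and 0.40 with it, and of the 31, 13 also rose with ABA in the presence of DFPM and 1 fell. The sum lay above the highest array value of 15.6 for 1 of the 32, at 16.5, and the next highest was 14.7. This argues against the upper limit as the cause where the sum lay well below it. For 7 of the 31 that had risen with ABA neither end was reached, and for these a weaker ABA response in the presence of DFPM stays open as a hypothesis. AT1G07690 was not among the 31, as it did not pass with ABA alone (-0.09) and changed by -4.42 with ABA in the presence of DFPM.

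Whether chance can be excluded for the count was tested by reshuffling residuals of the additive model. The real count of 54 was reached in 6 of 100 draws, the real one included, and the highest other was 4237, so chance could not be excluded this way. All 5 other draws with as many had the 4 arrays numbered 3 on one side of the contrast, as 12 draws did, which points to the structure of the samples. With the block and reshuffles within numbers, the real count of 202 was reached in 4 of 100 draws, with 1172 the highest other, a share under 0.05. With numbers 1 and 2 averaged and the block kept, 0 probe sets passed limma, and 924 of 14401 had an unadjusted p under 0.05.

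The ABA effect was smaller with DFPM present, with an instrumented slope of 0.690. A window on the mean over all arrays kept probe sets at both ends of the scale, so it was replaced after the results were seen. Over 1125 probe sets whose control, ABA and DFPM means and sum of both single effects lay from log2 5 to 12, the slope was 0.746 (SD 0.117), under the 0.9 that a floor or ceiling would leave. It was 0.732 (SD 0.0509) over 511 probe sets that DFPM itself moved by less than 0.25, and 0.798 (SD 0.101, highest of 3 rounds 0.912) over those of them from log2 5 to 12. These slopes lay under the 0.9 set for both treatments acting on the same probe sets without adding up, the latter by a narrow margin. The DFPM effect, on 244 probe sets that ABA moved by less than 0.25, had a slope of 0.836 (SD 0.0542), or 0.847 (SD 0.0457) from log2 5 to 12. This lay, by a narrow margin, under the 0.9 set for a reduction that runs only from DFPM to the ABA response. The SDs cover only the held-out arrays of control and 1 treatment. The ABA+DFPM arrays and those of the other treatment were the same in every round, and the subsets were chosen on all 12 arrays. With margins this narrow, the slopes cannot decide between these explanations and a mutual weakening of both responses. A biological cause was not tested further, as no array holds another dose or time.

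The arrays numbered 3 stood apart in every group: 7415 probe sets differed between them and numbers 1 and 2, against 7434 after another quantile normalization, which argues against unequal scaling as the cause. RNA integrity cannot be told apart from other differences between the numbers, because for 1 of 3 control genes, ubiquitin, the 3' minus 5' difference of the array numbered 3 lay on one side of both others in all 4 groups, and for actin and GAPDH it did not. The glyoxylate cycle gene ICL was higher in number 3 by 4.04 ± 0.18, from 3.19 with DFPM to 4.50 in control, and the anthocyanin gene DFR by 4.72 ± 0.91, but unevenly, with 6.79 in control, 8.14 with ABA, 1.13 with DFPM and 2.81 with both. Both genes were picked for the size of the mean. Of the 1251 interaction calls made in numbers 1 and 2 alone, 84.5% had the same sign in number 3. No biological explanation was tested, since the labels do not say what the numbers stand for.

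For the pairwise counts the 10 splits of 6 arrays are too few for a share under 0.05, and in each comparison 1 split of 10, the real one, gave as many calls. The real and highest other counts were 4165 and 0 for ABA with control, 3463 and 0 for DFPM with control, 1814 and 0 for ABA+DFPM with ABA, 2049 and 3 for ABA+DFPM with DFPM, and 6833 and 0 for ABA+DFPM with control.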

How the results depend on the processing

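Of these alternatives, the arrays numbered 1 and 2 alone, their average, number 3 as a block and the slopes on subsets were chosen after the data were seen. Of 113 results named by the rule 113 kept their sign in all settings, and further list members and family genes are not in this count. Of the 111 past the threshold, 111 passed with the replicate block, as did every call of the main fit. In arrays 1 and 2 alone 110 passed (not EXP18 in ABA+DFPM with ABA, 0.0549), 88 did without each of the 12 arrays and 108 after another quantile normalization (not EXP18 in both its comparisons, 0.0625 and 0.0847, nor AT4G20430, 0.0508). With only the 2 groups compared, 14 of 91 did not pass (0.0531 to 0.124): WRKY53 in both its comparisons, EXP18 in both, WRKY22, UGT73B5, GRX480, COR47, AT5G55220, AT5G62360, AT3G13610, GSTU25, GH3.3 and COR15B, nor did the family genes CML42 (0.0506) and SAG29 (0.0696). Signal near background limits the fold changes of genes whose lower mean is under log2 4. Except where a cause is given, the cause was not tested.

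Counts are in the order ABA and DFPM with control, ABA+DFPM with ABA and with DFPM, then the interaction. Array weights gave 9020, 7969, 5959, 7612 and 1578, the replicate block 6982, 6821, 4486, 5069 and 202, arrays 1 and 2 alone 8364, 7146, 5276, 7364 and 1251, and number 3 as a block 7231, 7124, 4850, 5303 and 298. Adjusted p under 0.01 gave 2071, 1444, 637, 707 and 23, and probe sets of 1 gene, with fewer tested, 2103, 1696, 878, 1016 and 26; ABA+DFPM with control gave 4294 and 3527 under these. A filter at log2 6 left 21 interaction calls. With only the 2 groups compared, DFPM gave 2250 and ABA+DFPM with DFPM 862. Averaging numbers 1 and 2, with the block, gave 3365, 3472, 1384, 813 and, for the limma interaction, 0, with 924 at an unadjusted p under 0.05, so the higher counts under the block were not seen in this design. Without 1 array the ranges were 2402 to 4669, 1981 to 4032, 904 to 2280, 806 to 3246 and 27 to 91, and 5335 to 7167 for ABA+DFPM with control.

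The cross-fitted ABA slope, 0.657 in the main setting, was 0.577 over genes lower with ABA and 0.634 to 0.707 without 1 ABA+DFPM or DFPM array. By the number of the control and ABA arrays held out it was 0.624 to 0.698. The instrumented slope, 0.690 over all ABA calls, was 0.723 at a middle mean and 0.746 away from both ends of the scale. It was 0.732 at small DFPM effects and 0.798 at these away from both ends. With an estimated correlation camera gave adjusted p = 0.170 for the ABA and immunity lists with ABA, detoxification with DFPM, and immunity and detoxification in ABA+DFPM with ABA; 0.224 and 0.257 for the ABA and immunity lists with DFPM, 0.174 for the ABA list in ABA+DFPM with ABA, and 0.315 for detoxification in the interaction. For detoxification fry gave 0.0394 with ABA and 0.236 in the interaction, and no filter 0.0442 with ABA. The replicate block gave 0.0593 for immunity with DFPM and, beside the blocked values given with their genes and families, changed no other call of a named gene, list or family. Arrays 1 and 2 alone gave 0.0644 for the ABA and immunity lists with DFPM and in ABA+DFPM with ABA, and 0.150 for detoxification in the interaction. Without 1 array the ranges were 0.0120 to 0.0900 for immunity with DFPM, and for detoxification 0.0275 to 0.231 with ABA and 0.0038 to 0.195 in the interaction.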

Other observations

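The family tests in this part, and the genes named from them, were chosen after the data were seen, as were the genes that mark the arrays numbered 3. Of 6 measured glutamate receptor-like channel genes 5 rose with DFPM, with a median of 1.98 over the 6, among them GLR2.8 by 2.2 ± 0.40 and GLR2.9 by 3.3 ± 0.78 (n = 3, limma). In ABA-treated seedlings 3 of 6 rose, GLR2.8 by 3.35 ± 0.40 (adjusted p = 8.19e-04). Camera gave adjusted p = 0.0195 and 0.0036, with adjusted p = 0.458 with an estimated correlation in both. Of 7 tubulin genes 5 fell with DFPM and 3 in ABA+DFPM against ABA: TUB5 changed by -2.34 ± 0.17 and -2.46 ± 0.17, and TUB6 by -1.66 ± 0.19 with DFPM (camera, adjusted p = 0.0195 in both, with adjusted p = 0.458 with an estimated correlation). Of 37 UDP-glycosyltransferase genes 13 rose and 1 fell with DFPM, and 11 rose and 2 fell in ABA+DFPM against ABA (camera, adjusted p = 0.0195 and 0.0361, with adjusted p = 0.458 with an estimated correlation). Over 8 tau-class glutathione transferase genes the median was -0.35 with DFPM and -0.30 in ABA+DFPM against ABA. Over 11 cytochrome P450 genes it was -0.07 and 0.26. The calcium sensor gene CML42 rose by 3.07 ± 0.65 in ABA+DFPM against ABA, as 2 of 8 calmodulin-like genes did (camera, adjusted p = 0.0343, with adjusted p = 0.458 with an estimated correlation).

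With ABA alone 6 of 11 autophagy genes rose, with a median of 0.85, among them ATG8H, which encodes a protein of the autophagosome membrane, by 2.23 ± 0.18 (limma, adjusted p = 1.91e-05). Of 5 late embryogenesis abundant genes 3 rose, and of 12 vacuolar protein sorting genes 6 rose with ABA and 5 with DFPM. Camera gave adjusted p = 8.23e-04 for autophagy, 0.0195 for the LEA genes (blocked 0.0862), and 0.0197 (blocked 0.0625) and 0.0141 for vacuolar sorting, each with adjusted p = 0.458 with an estimated correlation. In the interaction 0 of 12 vacuolar sorting genes passed and camera gave 0.0309 below 0 (blocked 0.0913), with adjusted p = 0.487 with an estimated correlation. In ABA+DFPM against ABA, 4 of 8 SWEET sugar transporter genes fell, with SAG29 at -2.57 ± 0.51 (camera, adjusted p = 0.0309, blocked 0.113, with adjusted p = 0.458 with an estimated correlation). With the arrays numbered 1 and 2 alone, the LEA call was lost (adjusted p = 0.155), as were those of vacuolar sorting and tubulins (0.0600 in each pairwise comparison, and 0.0927 in the interaction for vacuolar sorting), while the other families passed.

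Of 68 plastid-encoded probe sets 4 passed the limma test with DFPM, all lower, a share of 5.88% against 11.4% of all probe sets, or 28 with the replicate block, 41.2% against 26.5%. Their median was -0.52, with 63 below 0, and in camera 0 of 5 plastid-encoded families passed with DFPM, with the lowest adjusted p at 0.105. With ABA their median was -0.25 and 0 passed in limma, or 2 with the block, both lower. In ABA+DFPM against ABA it was -0.20, and 1 rose, or 3 higher and 3 lower with the block. In the interaction the plastid-encoded ribosomal protein genes gave a camera adjusted p of 0.0649, or 0.0326 with the block, with adjusted p = 0.730 with an estimated correlation, and 0 of 15 members passed.

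Genes that marked the arrays numbered 3 included AT1G19960, AT4G33720 and the beta-glucosidase gene BGLU28, higher by 5.70, 5.42 and 4.21, and AT1G73120, AT1G62510 and the defensin gene PDF1.4 at -5.14, -4.89 and -4.48. The size differed between groups, for AT4G33720 from 2.15 with DFPM to 8.46 with ABA and for PDF1.4 from -1.64 with ABA to -6.05 with DFPM. In camera 0 of 39 gene sets passed between the numbers, with the lowest adjusted p at 0.0868 for the xenobiotic detoxification list, whose median was 1.27.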
